A study of Mus musculus with 3 samples.

How the data were processed

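Bulk ATAC-seq values were analysed for 3 libraries, 1 per group: WT basal, Pten-deleted basal and WT luminal prostate cells. Tools named in the submitters' processing notes are Bowtie2 2.2.6, SAMtools, Picard, MACS2 2.1.0.20151222 and HTSeq, with builds GRCm38 and mm10, and the notes give no order or settings. The authors deposited normalized signal for 53767 regions, a single region set with a peak call per library, in a table of 72901 lines that repeats a region for each gene assigned to it. How genes were assigned, duplicate removal, read shifting and the normalization are not given in the sources used here. The deposited signal summed over distinct regions to 999880, 999813 and 999812 in the 3 libraries and came in whole multiples of what 1 read is worth in each. It is therefore called CPM, a count scaled by the total reads in regions, and reads were recovered from it, 100% of values being whole within 0.1 read. A region set called largely in the deepest library favours regions open in WT basal cells: 19092 regions were called in WT basal only, 5169 in luminal only and 440 in Pten-deleted basal only. The floor of 3 counts was 0.497 CPM in WT basal, 2.20 in Pten-deleted and 2.41 in luminal cells, taken per library.

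Coordinates are printed as the deposited table gives them, and whether they count from 0 or 1 is not given in the sources used here. Of 16529 gene names, 15897 were symbols of the RefSeq gene table (GRCm38.p6) and 423 synonyms only, and 209 matched neither. Positions relative to a gene come from that table, which holds gene starts and ends without strand, exons or introns. Distances are to the nearest gene end in kb.

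Ratios were taken as log2 of (CPM + pseudocount), with a pseudocount of 0.9536, which is 10 times below the table median of 9.536, so a log2 ratio understates differences of weak regions. Folds are ratios of CPM without pseudocount. A region or gene was called at 2-fold or more on the log2 scale. Counting intervals of a ratio are exact conditional 95% intervals from the recovered reads. Reads are not independent molecules, so counting intervals and floors cover counting error only. Other intervals are Wilson intervals of a share of regions or come from resampling regions. They treat regions as independent and hold no spread between libraries. A count model on the recovered reads was not fitted because 1 library per group leaves no residual degrees of freedom. A gene's value is the sum over its assigned regions, and a region can count for several genes. List medians were placed among 10000 random lists of equal size matched on mean signal in 20 bins, a description of these libraries. Noise expectations are means of 20 simulations at the real depths, with counting noise alone or with an added lognormal spread between libraries.

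Before the data were examined, the comparisons, the 2-fold rule, 19 gene lists, the rule for named genes and most of the other settings tried were fixed. The rule took, per comparison, the 10 regions with the highest and the 10 with the lowest ratio (with pseudocount) among regions with an assigned gene at or above the table's median, 1 per gene, up to 4 members of each list with the largest ratio at or above the median gene value, and Pten, Krt5, Krt14, Trp63, Krt8, Krt18, Nkx3-1, Ar and the 5 NF-kB subunit genes. Not all genes it takes are printed. List members past 2-fold but below the median gene value were named after their values were seen. Alternatives covered the fold, scaling, pseudocount, signal filter, sex chromosomes and the way genes were summarised. Motif shares and alternatives by distance to transcription start sites were planned but not run, because no genome sequence and no strand were used here. Distance to gene ends was used in their place.

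On simulated data with 200 changed regions at or above the median among 53767, the 2-fold rule recovered 45.5% of 2-fold, 97.0% of 3-fold and 99.0% of 4-fold changes for Pten-deleted against WT basal, 44.5%, 90.0% and 99.5% for luminal against WT basal, and 47.5%, 89.0% and 97.5% for Pten-deleted against luminal. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.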

Results

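Chromatin accessibility was measured by bulk ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in epithelial cells sorted from the mouse prostate. The 3 libraries were 1 of wild-type (WT) basal cells, 1 of basal cells taken 6 weeks after deletion of Pten in basal cells, and 1 of WT luminal cells, each from 100000 sorted cells pooled from several mice. Basal cells form the outer layer of the prostate epithelium and luminal cells the secretory inner layer, and Pten is the phosphatase that opposes PI3K signalling. The WT libraries came from CD1 mice and the Pten-deleted library from a line carrying the K5CreER and floxed Pten alleles, so mouse line and deletion cannot be separated. The table listed 53767 regions with 6034825 reads in regions for WT basal, 1363032 for Pten-deleted basal and 1244831 for WT luminal. The WT basal library was 4.43 times as deep as the Pten-deleted and 4.85 times as deep as the luminal library, and 48081 regions were called as peaks in it, against 23805 and 27170. Each group was 1 library, so no difference has a replicate check, no p-value is given, and regions or genes are called higher or lower by size alone, at 2-fold or more. Intervals in parentheses after a fold are exact 95% counting intervals and cover counting error only.

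The targeted gene was examined first. The region over an end of Pten (chromosome 19, 32755807 to 32757870, mouse build GRCm38/mm10) held 125 CPM in WT basal, 118 CPM in Pten-deleted basal and 156 CPM in WT luminal cells, a ratio of 0.942 (0.789 to 1.12) between the basal libraries. A region inside Pten (32788815 to 32789391) held 3.65, 2.93 and 16.1 CPM, with 4 reads in the Pten-deleted library. Which part of the gene the deletion removes is not given in the sources used here, so these regions do not check the deletion.

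The comparison of WT luminal with WT basal cells asks how the chromatin of these cell types differs. Keratin genes of basal cells were less accessible in luminal cells. Summed over its regions, Krt5 was 5.72-fold lower (3.43 to 10.3), Krt14 6.08-fold lower (4.12 to 9.36), Krt17 6.81-fold lower (4.50 to 10.8) and Krt15 4.01-fold lower (2.79 to 5.95). The Notch ligand Jag2 was 4.22-fold lower (3.47 to 5.18) and the hemidesmosome collagen Col17a1 4.02-fold lower (2.57 to 6.66). Among luminal genes, the tight junction gene Cldn3 was 2.94-fold higher (2.62 to 3.29), Prom1 2.65-fold (2.11 to 3.32), Dpp4 3.68-fold (2.70 to 5.01), the secretory genes Tgm4 20.2-fold (8.09 to 60.2) and Spink1 32.5-fold (14.6 to 85.4), and the calcium channel gene Trpv6 4.04-fold (2.12 to 7.63). Ar, Krt18, Nkx3-1 and Krt8 stayed below 2-fold, with log2 ratios of 0.91, 0.44, 0.34 and 0.10.

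The gene lists fixed before the data were examined gave the same contrast by group. Of 24 basal genes, 12 were at least 2-fold lower in luminal cells and 0 higher, and the list's median log2 ratio of -0.96 lay at percentile 0 of 10000 random lists matched on mean signal. Of 25 luminal genes, 6 were higher and 0 lower, with a median of 0.45 at percentile 99.99. NF-kB targets had a median of -0.27 (percentile 0.1), with 5 of 39 lower, among them Lcn2 at 8.56-fold (3.88 to 23.6), Icam1 at 3.88-fold (2.75 to 5.65) and Cxcl1 at 2.11-fold (1.63 to 2.76). Developmental regulators had a median of -0.33 (percentile 0.2), with 4 of 37 lower and 2 higher, and Bmp4 2.72-fold (1.92 to 3.98) and Fgfr2 2.39-fold lower (2.07 to 2.78). The epithelial-mesenchymal transition list had a median of -0.26 (percentile 0.62), with 5 of 18 lower, including Tgfb1 and Mmp14, and 2 higher, Zeb1 and Cdh2. Proximal luminal genes split, with Nupr1, Tspan8 and Cldn10 higher and Ly6d, Ly6a and Tacstd2 lower, and their median was -0.27 (percentile 0.81). The fibroblast list had a median of -0.36 (percentile 0.815) and the androgen response list 0.20 (percentile 97.6), although its members Pmepa1, Ndrg1 and Steap4 were at least 2-fold lower. The medians of the interferon response (0.068), innate immunity (0.10), AP-1 (-0.35), FOXO and PI3K (0.084), cell cycle (0.27), smooth muscle (0.074), endothelial (0.25), leukocyte (0.34), neuroendocrine (0.34), seminal vesicle (0.12) and housekeeping (-0.045) lists lay inside the central 95% of random lists. With the strongest region of each gene in place of the sum, the androgen response median was -0.022, and the fibroblast, proximal luminal and androgen response lists lay inside the random range. By the share of a list's regions at least 2-fold higher, the fibroblast (percentile 57.0), proximal luminal (percentile 89.4) and epithelial-mesenchymal transition (percentile 2.535) lists lay inside it, while the leukocyte list (35.7% of regions, percentile 98.315) and the smooth muscle list (11.8%, percentile 2.17) lay outside.

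At the level of regions, 9371 were at least 2-fold higher and 10506 at least 2-fold lower in luminal than in basal cells, where counting noise alone gives 649 and 2186, and noise with an added CV of 0.4 gives 5641 and 7204. Which side had more depended on the setting, with 9001 higher and 7832 lower where the counting interval excluded 1, 5723 and 5483 at 3-fold, and 10144 and 10130 at equal depth. Among regions at or above the table's median, the highest ratios included a region 6.63 kb from Oit1 (chromosome 14, 8385393 to 8385876) at 29.5-fold (15.9 to 59.7), a region inside Slc26a3 (chromosome 12, 31458511 to 31459126) at 31.2-fold (15.4 to 71.7) and a region 37.7 kb from the transcription factor gene Tfcp2l1 (chromosome 1, 118589737 to 118590242) at 36.4-fold (15.5 to 104). On the other side, regions near March10 and Rbbp8 and inside Pik3r1 held 0 luminal reads and were at least 12.5-fold, 11.8-fold and 10.9-fold lower against the luminal floor of 3 counts. A region inside Dscaml1 was 36.7-fold lower (12.5 to 179). Among regions at or above the table's median signal, 2727 were higher and 4905 lower in luminal cells. That filter takes the mean over libraries of which more are basal than luminal. It passes basal-high regions more easily, so this balance does not show a lean to basal cells.

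**Figure D1:**
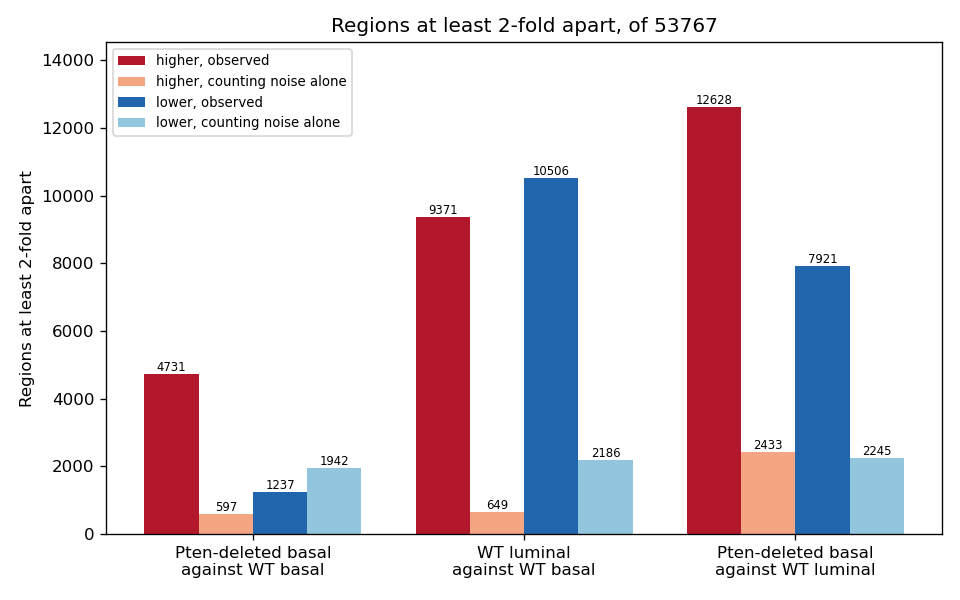
Regions at least 2-fold higher or lower in each comparison (bars from 0, number of regions), observed and as given by counting noise alone at the real depths. In the Pten comparison 4731 regions were higher against 597 by noise, and 1237 were lower against 1942 by noise.

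The comparison of Pten-deleted with WT basal cells asks what differs in basal chromatin after the deletion. The main basal keratins were close to their WT level, with Krt5 at 1.03-fold (0.819 to 1.29) and Krt14 at 1.16-fold (0.984 to 1.35). Trp63, the gene of the basal master regulator p63, was 2.83-fold higher (2.15 to 3.73), with most of the gain in a region 59.0 kb from the gene (chromosome 16, 25624008 to 25624761) that held 6.96 CPM in WT basal and 38.9 in Pten-deleted cells, and 1 read in luminal cells. A region 18.4 kb from the integrin gene Itgb1 (chromosome 8, 128666601 to 128667255) was 4.59-fold higher (3.09 to 6.83). Among regions at or above the table's median, those with the highest ratios included regions near Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1 (chromosome 8, 35293338 to 35294070, 81.6 kb away), at 32.1-fold (17.5 to 64.5), near the chemokine gene Ccl28 at 16.2-fold (8.43 to 33.8), near Hhipl1 and Ccdc85c at 11.8-fold (6.38 to 23.0) and near Bcl10, an adaptor of NF-kB signalling, at 14.8-fold (6.83 to 35.3). Cytokine receptor genes were also among them, with a region inside Il31ra that was assigned to Il6st as well at 8.47-fold (5.00 to 14.7), and a region inside the decoy receptor gene Il1r2 at 7.67-fold (3.92 to 15.6). Lower regions included one inside Igsf21 at 8.47-fold (4.24 to 19.8), one near Gna14 at 6.38-fold (2.42 to 23.8), one near Cox7a2l at 5.28-fold (2.90 to 10.7) and one over an end of Cwc22 at 4.06-fold (2.67 to 6.47).

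**Figure D2:**
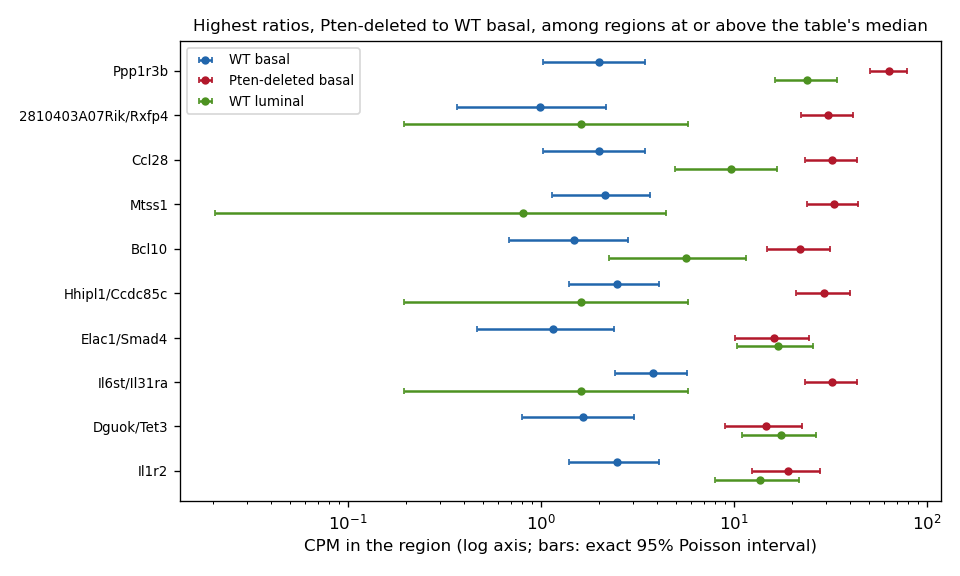
CPM (log axis) in the 10 regions with the highest ratio of Pten-deleted to WT basal signal (with pseudocount) among regions with an assigned gene at or above the table's median, 1 per gene, with 1 point per library with exact 95% Poisson intervals. The region near Ppp1r3b reached 63.8 CPM in the Pten-deleted library, against 1.99 in WT basal and 24.1 in WT luminal cells.

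By gene list, differences between the basal libraries were small. Innate immunity genes had a median log2 ratio of 0.26 (percentile 99.72), with Cd14 at 1.33-fold (1.04 to 1.69), the flagellin receptor gene Tlr5 at 1.30-fold (1.03 to 1.62) and the only member past 2-fold, S100a9, at 2.66-fold (1.18 to 5.71). Basal genes had a median of 0.20 (percentile 99.98), with Trp63 the only 1 of 24 past 2-fold, and proximal luminal genes 0.20 (percentile 98.78), led by Cldn10 at 1.62-fold (1.22 to 2.14) and Cd44 at 1.53-fold (1.30 to 1.79). Developmental regulators had a median of 0.11 (percentile 99.915) and housekeeping genes -0.17 (percentile 1.51). NF-kB targets lay inside the central 95% of random lists, with a median of 0.10 (percentile 95.85). Traf1 at 2.48-fold (1.19 to 4.96) and Ptgs2 at 2.75-fold (1.56 to 4.76) were higher, Bcl2l1 was 1.37-fold lower (1.22 to 1.55), and the subunit genes Nfkb1, Nfkb2, Rela, Relb and Rel had log2 ratios of 0.24, -0.23, 0.20, -0.10 and -0.17. Luminal genes had a median of 0.10 (percentile 95.895), with Spink1 at 5.69-fold (1.89 to 18.0) and Prom1 at 1.57-fold (1.20 to 2.04), while Ar, the androgen receptor gene, had a log2 ratio of 0.44, Krt8 -0.14, Krt18 -0.060 and Nkx3-1 -0.22. Ar, Krt8, Krt18 and Nkx3-1 also differed less than 2-fold between luminal and WT basal cells, so they mark luminal chromatin weakly here. Single members at least 2-fold higher in other lists were Gbp2 at 3.07-fold (2.03 to 4.60), Cdh2 at 3.32-fold (1.58 to 6.82) and Cdkn2a at 2.70-fold (1.57 to 4.55). Markers of other cell types were inside the random range, with medians of 0.23 for fibroblast, 0.24 for smooth muscle, 0.28 for endothelial, 0.035 for leukocyte, 0.14 for neuroendocrine and -0.20 for seminal vesicle genes, but the endothelial genes Kdr and Eng were 2.95-fold (1.39 to 6.09) and 2.09-fold (1.56 to 2.77) higher, and the fibroblast gene Tcf21 and the seminal vesicle gene Svs4 were 2.93-fold (0.735 to 25.5) and 4.51-fold (0.723 to 187) lower on 2 reads and 1 read. The interferon response (-0.032), AP-1 (-0.13), epithelial-mesenchymal transition (0.16), FOXO and PI3K (-0.055), cell cycle (-0.010) and androgen response (0.075) medians were also inside it. These 5 lists outside the random range became 0 when each gene was read from its strongest region, where the developmental median was -0.095, and 3 after quantile normalization, of which 2 were among the 5. With random lists matched on the number of regions, 3 of the 5 stayed outside. By the share of a list's regions at least 2-fold higher, 0 lists lay outside.

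**Figure D3:**
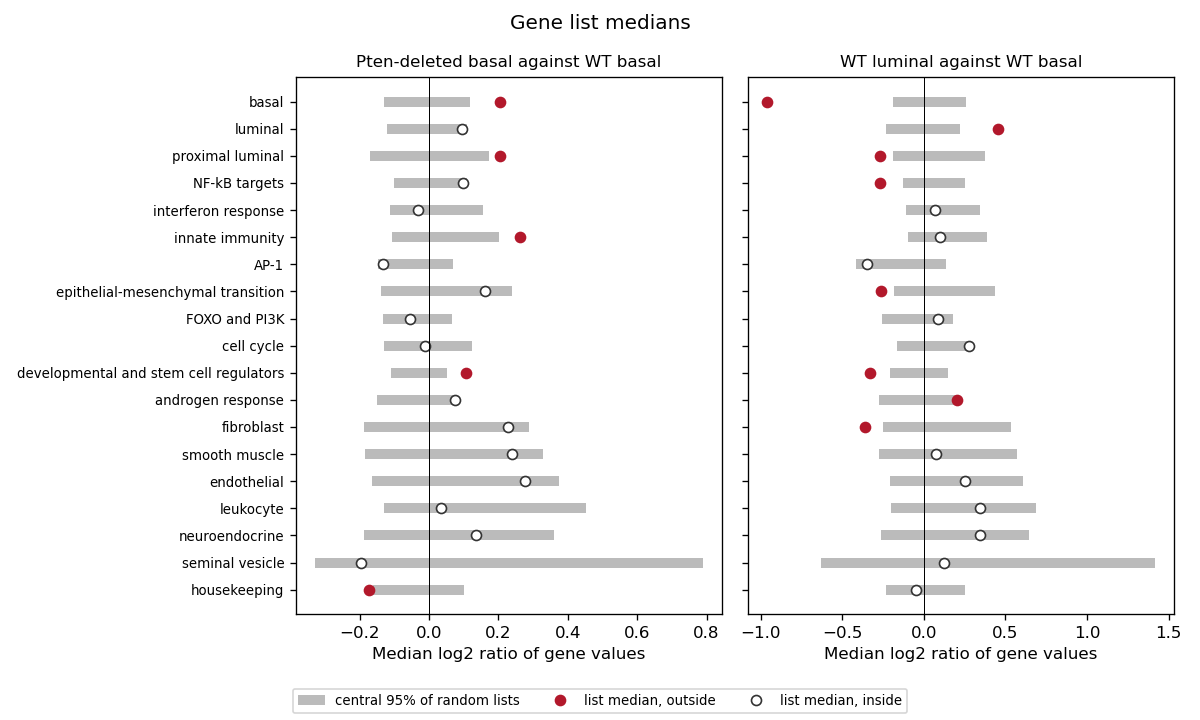
Median log2 ratio of each gene list (points) with the central 95% of 10000 random lists matched on mean signal (grey bars), for Pten-deleted against WT basal (left) and WT luminal against WT basal (right). The basal list lay at 0.20 on the left and -0.96 on the right.

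Over all regions, 4731 were at least 2-fold higher and 1237 at least 2-fold lower in Pten-deleted than in WT basal cells, and the counting interval excluded a ratio of 1 for 3832 and 584 of them. Counting noise alone gives 597 higher and 1942 lower, or 328 and 408 where the interval excludes 1. With an added spread between libraries, noise gives 1616 and 3155 at CV 0.2 and 5455 and 6902 at CV 0.4. The last are above the observed counts in both directions. Where the interval excludes 1, this noise gives 1227 and 1362 at CV 0.2 and 4834 and 4709 at CV 0.4. The 1237 lower regions were thus fewer than counting noise alone gives, and the 584 fewer than noise at CV 0.2. The balance depends on scaling, since quantile normalization gave 2807 higher and 2713 lower, a share higher of 50.9% in place of 79.3%. Above the table's median signal, 1007 regions were higher and 249 lower.

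The 2 comparisons with WT basal were then set against each other, to ask whether regions open in luminal cells were more accessible after Pten deletion. Of the 9371 regions at least 2-fold higher in luminal cells, 2361 were also at least 2-fold higher in Pten-deleted basal cells (25.2%, 95% Wilson interval 24.3 to 26.1), against 5.34% of all other regions. Much of that gap went with weak WT basal signal, since regions up to 3 CPM in WT basal were higher in the Pten-deleted library at every luminal level. Their mean was 3.79 against 1.65 CPM where luminal signal was 10 to 30 CPM. It was 4.22 against 2.27 CPM where luminal signal was also up to 3 CPM. Some of the 2437 regions weak in both WT libraries may be in the set only through a call in the Pten-deleted library, so selection can raise the last mean. Over the whole set, 440 regions were called in that library only, so this cannot hold for most of the 2437. With other regions matched on WT basal signal, which was possible for 6252 of the 9371, the shares were 17.2% and 12.9%, a difference of 4.32 points (3.29 to 5.37 by resampling regions). They were 16.8% and 11.1% without regions called only in the Pten-deleted library, and 6.98% and 3.79% among regions called in WT luminal, where 2034 could be matched. Matching was incomplete, as the matched others held a mean of 6.14 CPM in WT basal against 5.53 in the first of these. Among regions called in WT luminal they held 12.7 against 10.6 CPM. Such gaps can lower the share of the others. The matched sets also left out all regions below 1.66 CPM in WT basal, and below 5.30 CPM among regions called in WT luminal. The share of luminal-higher regions fell from 25.2% to 17.2% through the regions left out, so the weakest regions are not covered by the matched shares. The regions near Ppp1r3b and Il1r2 and the region over an end of Elac1 were among the 2361 regions higher in both. The last held 1.16 CPM in WT basal, 16.1 in Pten-deleted and 16.9 in luminal cells. The luminal gene Tgm4 held 6 reads in WT basal and 1 read in Pten-deleted cells. In the other direction, 359 regions were lower in both and 545 regions lower in luminal cells were higher after deletion. Both comparisons share the WT basal library. Unchanged libraries simulated against it gave 73 regions higher in both with counting noise alone, 263 with CV 0.2 and 1583 with CV 0.4, and independent lists give 825. At CV 0.4 they also gave 1988 regions lower in both, against the 359 observed. The covariance of the log2 ratios across regions was 0.21, against 0.039 simulated with counting noise, 0.10 with CV 0.2 and 0.27 with CV 0.4. The simulated values come from the shared library and noise alone. How much of the 0.21 they account for therefore depends on the spread assumed. Fewer regions met both criteria after quantile normalization (1520) and among regions at or above the table's median (499), and more at equal depth (3619).

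Set directly against WT luminal cells, the Pten-deleted library kept a basal pattern at the markers. Krt14 held 147 CPM against 20.9 in luminal cells and Krt17 141 against 18.5. In all, 12628 regions were at least 2-fold higher and 7921 lower in Pten-deleted basal than in luminal cells, where counting noise gives 2433 and 2245, and noise with an added CV of 0.4 gives 7436 and 7286. Quantile normalization gave 10328 and 9843, a share higher of 51.2% in place of 61.5%. Regions inside Pik3r1 and Tgfbr2 and near Ippk and Bicd2 held 0 luminal reads and were at least 13.4-fold, 12.5-fold and 13.4-fold higher against the floor of 3 counts. A region inside Vdr, the vitamin D receptor gene, was 60.3-fold higher (10.4 to 2416), with 1 luminal read. Regions inside Npepps and Mtmr12 were 31.8-fold (8.40 to 268) and 12.6-fold (6.83 to 26.0) lower, with 2 and 11 reads in the Pten-deleted library. Across regions the log2 signal of the Pten-deleted library correlated with WT basal at Pearson r = 0.914 and with WT luminal at r = 0.649, and regions are not independent replicates.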

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

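The tests at equal depth, with counting intervals, by distance to gene ends, without luminal-higher regions, by the share of a list's regions and with matched WT basal signal were chosen after the data had been seen, and the others before. No paired analysis was possible because each group is 1 library. Regions at least 2-fold apart numbered 5968 for Pten-deleted against WT basal, 19877 for luminal against WT basal and 20549 for Pten-deleted against luminal. In the same order they became 16055, 29843 and 31138 at 1.5-fold, 1294, 11206 and 10854 at 3-fold, 221, 5498 and 5534 with a pseudocount 10 times larger, 1256, 7632 and 7775 among regions at or above the table's median, and 817, 3036 and 3222 within 1 kb of a gene end. These settings change the size asked for or the regions counted. The other 24 counts were within 1.5 times of the first-named ones, and equal totals changed no count. Quantile normalization lowered the share higher from 79.3% to 50.9% in the Pten comparison and from 61.5% to 51.2% against luminal cells. Keeping regions at or above the median, a filter that passes basal-high regions more easily, lowered it from 47.1% to 35.7% for luminal against basal. Rescaling to a median log2 ratio of 0 gave 3798 higher and 1667 lower in the Pten comparison. The 2361 regions higher in both comparisons became 5573 at 1.5-fold, 541 at 3-fold, 1520 after quantile normalization, 499 at or above the median and 3619 at equal depth. The share of other regions higher in the Pten-deleted library, 5.34%, became 12.9% when matched on WT basal signal, 11.1% also without regions called only in the Pten-deleted library and 3.79% among regions called in WT luminal. The 5 lists outside the random range in the Pten comparison became 0 by strongest region, 3 after quantile normalization, of which 2 were among the 5, and 0 by share of regions. Matching random lists on the number of regions gave 5, of which 3 were among the 5. By strongest region the developmental list turned to -0.095 (Pten comparison) and the androgen response list to -0.022 (luminal comparison). The cause of these changes was not tested. The lists of the luminal comparison outside the range numbered 6 to 9 in the settings run, against 8, but only 5 of the 8 stayed outside by strongest region and 5 by share of regions, 6 with the larger pseudocount and 7 when matched on the number of regions. Of the values of single genes under other settings, 493 stayed inside the gene's counting interval and 63 left it, and 0 of those from genes at 2-fold or more changed sign. Of list medians, 227 moved by less than the distance from the centre to the edge of their random range and 18 by more, and the 2 above changed sign among lists outside the random range. Alternatives by transcription start site and for motif shares were not run.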

Other observations

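Of the tests here, 4 were chosen only after the result was seen: carry-over of luminal cells, alone and on top of background, background against regions called in WT luminal, and background in regions weak in WT luminal. The split by luminal signal was also made afterwards. The counts of regions per gene were also made after the data were seen. Over all regions 8.80% were at least 2-fold higher in Pten-deleted than in WT basal cells, and the genes named here were picked from those with the most higher regions. The NKG2D ligand genes Raet1d and H60b had 5 of 5 and 5 of 6 regions higher, the cytokine gene Lif 5 of 15 and the integrin gene Itga2 4 of 8, with 0 lower, and quantile normalization gave the same counts. The tropomyosin gene Tpm1 had 7 of 22 higher and 1 lower, but 3 and 1 after quantile normalization. Vtcn1, a T cell inhibitory ligand gene, had 6 of 13 higher, and 0 after it. Alpl had 5 of 13 and the glucose transporter gene Slc2a1 4 of 18, and 4 and 2 after it, each with 1 lower. Irs2, an adaptor of insulin signalling, had 4 of 27 higher and 3 lower, and 3 and 4 after it. Regions assigned to several genes count for each. Whether the counts of Raet1d and H60b rest on the same regions was not examined, so they cannot be taken as 2 separate observations. Mouse line and deletion cannot be separated for any of these genes.

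More regions were higher than lower in the Pten-deleted library in each of 4 classes of luminal signal, with 1432 higher and 468 lower in the weakest class and 293 and 89 in the strongest, while the median log2 ratio was 0.24 in the weakest class and -0.099 in the strongest. A difference in depth is argued against as the cause, since at equal depth regions higher were still 3.84 times as many as regions lower (3.68 to 4.06). Added background reads remain open, tested by the excess of Pten-deleted CPM over 0.898 times WT basal CPM. That factor is the ratio of Pten-deleted to WT basal summed signal in regions over 30 CPM in WT basal. Among 29621 regions up to 10 CPM in WT basal the mean excess of the longest regions, of 3 equal classes by length, was 1.83 times that of the shortest (1.76 to 1.91), where their lengths differed 2.43 times. Because WT basal is the denominator of the ratio, regions up to 10 CPM in WT luminal were also taken, and gave 1.73 times (1.64 to 1.83) for lengths that differed 2.69 times. There the factor was 0.906, from regions over 30 CPM in WT luminal. A real gain in proportion to signal can also grow with region length, so these values do not favour background over it. Background as a part of the excess stays open, and Pten deletion and mouse line stay open as untested. Scaling stays open too, since the classes were counted on the deposited scale. Over all regions quantile normalization gave 2807 higher and 2713 lower.

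Regions strong in luminal (20 CPM or more) and weak in WT basal cells (up to 3 CPM) carried 4.95 CPM in the Pten-deleted library against 1.99 in WT basal over 422 regions. The background test written beforehand gave -2.39 CPM (-3.20 to -1.63) against matched luminal-weak regions, but it is void, because 25.1% of the matched regions and 0% of the luminal-strong ones were called in the Pten-deleted library only. Against regions called in WT luminal, a set chosen after that result, the difference was 0.758 CPM (0.342 to 1.20), and 0.410 CPM (-0.0162 to 0.852) once lengths were equalised, so background and a luminal-related gain cannot be told apart. Luminal cells carried over could also contribute and stay open, as do mouse line and Pten deletion: with a single share of 12.6%, 1.42% of regions (0.653 to 3.07) lay above it by more than counting error, but the luminal-weak regions set beside them (7.90% above their own mean excess, 7.12 to 8.76) come from the void set. With background added and a share of 4.25%, 4.74% lay above it (3.09 to 7.21) against 1.18% of luminal-weak regions (0.838 to 1.66), or 1.90% (0.964 to 3.70) at the share's upper bound of 6.76%. Chance gives at most 2.5%, because the rule allows for counting error in both the Pten-deleted and the luminal reads. A percentage below 2.5% therefore does not favour carry-over.

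There were 106 regions at least 4-fold higher in Pten-deleted cells than in both WT libraries, by ratios with pseudocount. Their counting interval against WT basal also had to lie above 2. Regions assigned to Col24a1, Itgb1, Trp63 and Mtss1 were among them. Many of the 106, the Mtss1 region among them, were called in the Pten-deleted library only, a class of 440 of the 53767 regions. Such regions are in the set through the same signal that makes them high here, and no noise count was made for the 106. A larger copied segment would raise their neighbours too. The median log2 ratio of 365 other regions within 50 kb, with the 106 themselves left out, was 0.22 (0.16 to 0.35). Over all regions it was 0.10. This argues against copied segments as the general cause, but not at single loci or for segments too short to hold another region. A difference between mouse lines may also give such regions, and it cannot be told apart from Pten deletion because 0 libraries came from the Pten line without deletion.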
